A study of Drosophila melanogaster with 2 samples.

How the data were processed

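The series holds chromatin immunoprecipitation with sequencing from whole Drosophila melanogaster prepupae of mixed sex. Per the labels, the flies carried an Eip93F gene with an inserted GFP exon, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the Eip93F-GFP fusion protein was precipitated with an antibody against GFP. The labels name 2 biological replicates of 1 group, so the replicates were compared with each other and no comparison between groups was made. Nothing in the labels says whether the replicates came from separate crosses or days.

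The deposited peak lists give, per the notes deposited with them, the position of each peak, a summit and the caller's own signal per peak. The signal was made by the authors' peak caller from the alignments of 1 replicate, or of both replicates together, against a control alignment. Its level is comparable only within a list. It was used to rank peaks, to compare medians of classes of peaks within a list, and to correlate the lists of the replicates across sites, by rank and on the log2 scale. The deposited lists also hold a −log10 (q) value per peak, which the authors' caller gave within each list. In the reproducible set on dm6 these q values ran from 0.000943 to 0.0357. The aligner, the peak caller and their versions are not given in the sources used here. No read counts came with the peak lists, so the depth of each library is unknown, and the intervals given for shares of peaks cover counting error only.

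The authors called each replicate separately and both replicates pooled, on the genome builds dm6 and dm3. Each of these lists holds 30000 entries, background included. From them the authors derived a reproducible set of 3401 peaks on dm6 and 3198 peaks on dm3 by the irreproducible discovery rate. Each reproducible set was checked against its pooled list. All 3401 and all 3198 of its peaks were found there, and no other pooled entry had a signal as high as its lowest. Because that set was chosen from reads of both replicates, its share found in a single replicate is not an independent test. The leading peaks of each replicate's own list were therefore also compared directly.

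Peaks on dm6 were placed on the Ensembl release 115 annotation of the same assembly, without transposable elements. A summit within 500 bp of any annotated transcription start site (TSS) was called promoter. Other summits were called exon, intron or intergenic, in that order. Shares were set against 1000 random placements of as many positions on the same arms, with a two-sided permutation p whose smallest value is 0.002. Signal at promoter peaks and at all others was compared by the difference of medians with 100000 permutations. Arm densities carry exact Poisson intervals with a confidence level of 95%, and the X was compared with the autosomes by an exact binomial test.

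A gene was said to hold a peak when a summit lay in it or within 1000 bp of it. The 13968 protein-coding genes on the 7 arms were the background. For 18 gene lists, the number of genes with a peak was set against 10000 random lists matched on gene span in 20 bins, two-sided, with a smallest p of 0.0002, and adjusted over the 18 lists by the Benjamini-Hochberg method. The lists covered the ecdysone response, juvenile hormone and metamorphic timing, ecdysteroid synthesis, autophagy, cell death, Hox genes, wing disc patterning and growth, chitin and cuticle, salivary gland glue and puff genes, fat body, muscle, neuron, glia, hemocytes, testis, cytoplasmic ribosomal proteins, chemosensory receptors and the cell cycle. For 17 preset sequence words and all 2080 6-mers, counted with their reverse complements, the share of peaks with the word within 50 bp of the summit was set against the mean of 2 windows of equal size centred 500 bp to either side. The test was McNemar's exact test against 1 of these flanks drawn per peak, with Benjamini-Hochberg adjustment. Calls were made at an adjusted p under 0.05.

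The genes named were Eip93F, the protein-coding gene with the TSS nearest to each of the 20 peaks with the highest signal, the 10 protein-coding genes with the most summits, and for each list up to 4 members with the strongest peaks. For lists of 10 genes or fewer, members without a peak were named too. The 10 6-mers with the smallest adjusted p among those higher at summits were named, with ties broken by gene symbol. Groups, tests, lists, words, the naming rule and the alternative settings given next were fixed before the data were examined. The alternatives were other overlap rules, promoter distances of 250 and 1000 bp, protein-coding TSSs alone, the 1700 peaks with the highest signal, the 3401 leading peaks of 1 replicate alone, other rules that link peaks to genes, Fisher's exact test, windows of 25 and 100 bp, flanks at 1000 bp, random windows matched on annotation class and GC content within 2 bases, the gene span without flanks for the genes with the most summits, and the dm3 lists.

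Further tests were added after values had been seen. These were the direct comparison of the leading peaks of the replicates, draws from the pooled entries outside the reproducible set in place of random positions, a set of 3401 pooled entries that starts just past the 10000 leading ones, the comparison of the left with the right flank, and 6 further gene lists. Those lists covered insulator and architectural proteins, Polycomb and Trithorax group genes, heat shock and chaperone genes, the circadian clock, insulin and TOR signalling, and antimicrobial peptides and immune receptors. The words CTTATC and ACAGTG and the leading members of the added lists were named outside the naming rule. The leading list of replicate 2 holds 1 mitochondrial entry, so 3400 of its peaks were placed on the arms.

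The tests were tried on simulated data. Of 20 6-mers planted in 2% of flank windows, 11 of 20 were called, and all 20 were called when planted in 5% of windows. In that second simulation 43 further 6-mers were called, of which 41 overlapped a planted word. Of 200 random lists of 31 genes, 9 gave a permutation p under 0.05, and all 200 did after peaks were given to 16 of their genes. Those lists were drawn from all background genes, so the length matching was not tried on lists of mostly long genes. Random positions used as peaks gave a permutation p under 0.05 in 3 of 160 class tests. Shuffled promoter labels did so in 5 of 100 trials. Tested without any summit, the left flank against the right flank gave 0 of 2080 6-mers past the adjusted threshold of McNemar's exact test and 84 at an unadjusted p under 0.05.

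Coordinates are 1-based on dm6. The dm3 lists were used only for counts per arm, replicate agreement, the check against the pooled list and a description of peaks outside the arms. No dm3 genome was used here, and no coordinate was converted. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.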

Results

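Eip93F encodes E93, a transcription factor induced by the steroid hormone ecdysone that acts during metamorphosis. Its binding sites were measured in whole prepupae, the stage that follows the end of larval life, by chromatin immunoprecipitation of an Eip93F-GFP fusion protein in 2 biological replicates. The reproducible set on dm6 held 3401 peaks, with signals from 89.8 to 1529 and a median of 129. The median peak was 410 bp wide. The signal is the authors' own score per peak, and its level is comparable only within a list. In each protein-coding gene and the 1000 bp around it, summits were found for 2774 of 13968 genes, or 19.9%. A summit within 500 bp of a TSS was found for 1768 genes.

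The strongest peak lay in an intron of CG11050, on arm 2L at 6612384 to 6612932, with a signal of 1529 and ranks of 1 and 2 in the lists of replicates 1 and 2. The 41 bp centred on its summit, 6612697 to 6612737, read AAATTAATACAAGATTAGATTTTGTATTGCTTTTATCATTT. The next peak lay 49 bp from the TSS of Ugalt, a UDP-galactose transporter, on the X at 2703726 to 2704055, in intergenic sequence, with a signal of 1495 and ranks of 2 and 1. The peak of rank 3 lay in an intron of ush, which encodes a partner of GATA factors, on 2L at 480937 to 481262, and ranked 3 in each replicate. The nearest TSS to it was that of cbt, 1374 bp away. Its summit sequence, 481042 to 481082, was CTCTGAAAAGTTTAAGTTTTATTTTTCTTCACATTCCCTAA.

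Among the other genes nearest to the 20 strongest peaks, the Polycomb group gene ph-p held a promoter peak in its intron on the X at 2137198 to 2137518 with a signal of 1097. Chro, which encodes a chromodomain protein, held 1 in its 5′ UTR on 3L at 22878737 to 22879089 with a signal of 1073. The peak at osa, which encodes a subunit of the Brahma remodelling complex, lay in an intron of that gene and in an exon of an overlapping long non-coding RNA, on 3R at 17704255 to 17704568, with a signal of 986. The peak near the TSS of the heat shock gene Hsp27, on 3L at 9383734 to 9384064, had a signal of 1013. Other nearest genes were CenG1A, CG1888, CG18549, CG32772, Lk6, CG13323, CG14100, Gapdh2, PNPase, eEF1gamma, CG4004, CG11362 and CG13921, with signals from 804 to 1100. Of the 20 peaks, 12 lay in promoters, 5 in introns, 2 in exons and 1 between genes. Each had a rank of 30 or better in both replicates.

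The replicates were compared to see how far the peak list could be repeated. Of the 3401 reproducible peaks, 2777 (81.7%) had their summit in a peak among the 3401 leading peaks of replicate 1 and 2725 (80.1%) in those of replicate 2. After a shift of the peaks by 20000 bp the shares were 2.15% and 2.23%. Both leading lists held 2185 peaks (64.2%), and 84 peaks were in neither. Compared directly, with no use of the pooled reads, 65.6% of the leading peaks of replicate 1 were among those of replicate 2, and 65.0% the other way round. Of the leading 100 peaks, 72% of those of replicate 1 were shared. By summit, 260 leading peaks of replicate 1 (7.64%) were absent from the full list of replicate 2, and 202 of replicate 2 (5.94%) from that of replicate 1. With 1 bp of overlap these counts were 148 and 76. Across the 3332 of the 3401 reproducible peaks that were present in both full lists, the signals of the replicates had a Spearman rho of 0.488 (permutation p = 0.0001, the smallest the permutations can give) and a Pearson r of 0.613 on the log2 scale. That correlation is across sites, which are not independent replicates, and these sites were chosen by their signal in the pooled reads, so it does not describe the full lists.

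**Figure D1:**
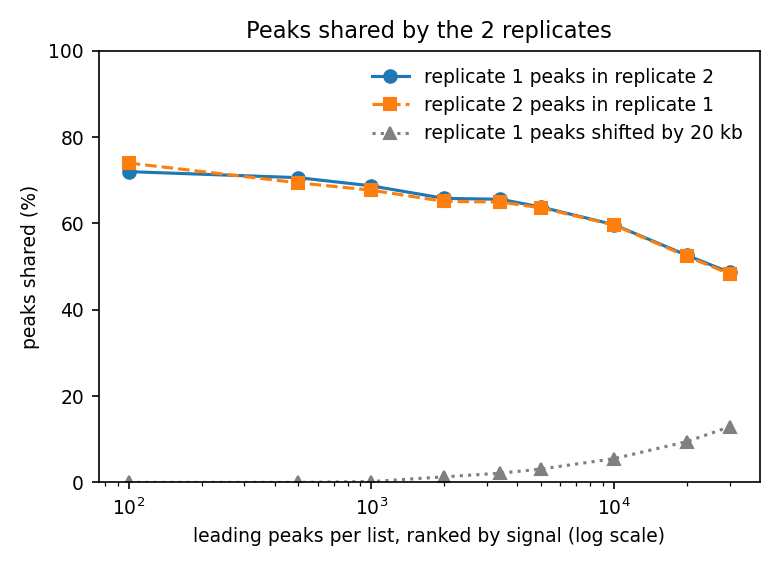
Share of peaks (%, vertical axis) that 1 replicate's leading peaks had in common with the other's, against the number of leading peaks taken from each list (log scale). Circles and squares show the 2 directions, and triangles show replicate 1 peaks shifted by 20 kb. The share fell from 72% at 100 peaks to 48.6% at 30000 peaks, where shifted peaks gave 12.9%.

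Summits were placed on the annotation to see where in the genome Eip93F-GFP was found. Promoters held 1601 of the 3401 summits, or 47.1% (Wilson interval 45.4 to 48.8%), against 13.6% of random positions. Exons away from a TSS held 106 summits (3.12%) against 19.7%, and intergenic sequence held 367 (10.8%) against 27.3%. For these 3 classes the permutation p was 0.002, the smallest the placements can give. Random positions came from all sequenced bases of the arms, with no filter for mappability. Draws from lower-ranked pooled entries gave nearer shares, 25.3% for promoters, 10.95% for exons and 17.6% for intergenic sequence (permutation p = 0.002 for each). Introns held 1327 summits (39.0%) against 39.4% of random positions (permutation p = 0.657). The replicates' own leading lists had 47.7% and 47.8% of summits in promoters. Of the 106 exon summits, 8 fell in coding sequence, 35 in 5′ UTRs, 32 in 3′ UTRs and 31 in non-coding exons. The median distance to the nearest protein-coding TSS was 746 bp, and 636 summits (18.7%) lay more than 5000 bp away. The intron share depended on the promoter distance. It was 44.2%, above random, with promoters of 250 bp and 31.2%, below random, with 1000 bp, each with a permutation p of 0.002. The exon share was 1.62% with 1000 bp.

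**Figure D2:**
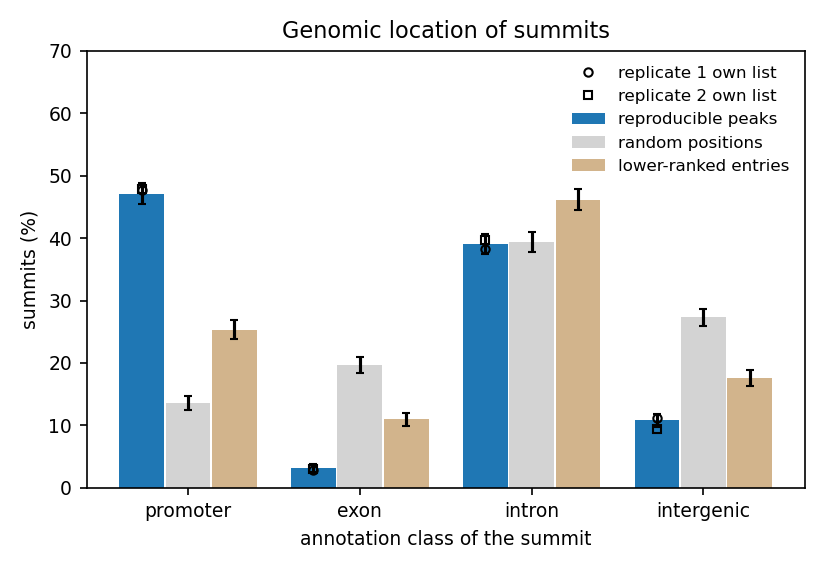
Share of summits (%, vertical axis) per annotation class for the reproducible peaks (Wilson 95% intervals), random positions and draws from the lower-ranked entries of the pooled list (bars span the central 95% of 1000 draws). Open circles and squares are each replicate's own leading peaks. Promoters held 47.1% of reproducible summits, 13.6% of random positions and 25.3% of lower-ranked entries.

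Within the reproducible set, promoter peaks were about as strong as the others. That set was itself cut by this signal, so the comparison does not cover the whole pooled list. Promoters held 47.1% of its summits, against 25.3% in draws from the lower-ranked pooled entries. The median signal of promoter peaks in the set was 131 over 1601 peaks, against 128 over the other 1800 peaks, a difference of 2.51 (two-sided permutation p = 0.146). In the replicates' own lists the differences were 1.69 (permutation p = 0.107) and 1.89 (permutation p = 0.0608). Among the 1700 strongest peaks the difference was 8.21 (permutation p = 0.0688).

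The X chromosome and the autosomes held peaks at about the same density. The X had 597 peaks, or 25.4 per Mb, and the autosomes 2804, or 25.4 per Mb, a ratio of 0.998 (exact interval 0.912 to 1.09; exact binomial p = 0.982). Densities ran from 24.5 per Mb on 3R (exact Poisson interval 22.8 to 26.2) to 27.5 per Mb on 2L (25.4 to 29.7), with 24.8 on 2R and 26.2 on 3L. Chromosome 4, the small and largely heterochromatic autosome, had 8 peaks, or 5.93 per Mb (2.56 to 11.7), fewer than its length gave (exact binomial p = 3.11e-07). That test was made for each arm with no adjustment, and 2L held more peaks than its length gave (exact binomial p = 0.00381). The density of chromosome 4 relative to all arms was 0.24, and 0.12 with the 1700 strongest peaks. The leading lists of replicates 1 and 2 had 10 and 9 peaks there. The Y had 0 peaks and no entry of any rank in any list, so its count says nothing about binding there.

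Genes of the ecdysone response held peaks more often than other genes of the same length. Of 31 such genes, 22 (71.0%) held a peak, against a mean of 10.7 in length-matched lists (ratio 2.06; permutation p = 0.0002, the smallest the lists can give; adjusted p = 0.0018). They held 100 summits in all. The strongest was in an intron of the nuclear receptor gene Hr4, on the X at 1951790 to 1952057, with a signal of 767 and ranks of 24 and 27 in the replicates. Eip78C and Eip75B, which encode ecdysone-induced nuclear receptors, held intronic peaks on 3L at 21253747 to 21254049 (signal 745) and 18011720 to 18012049 (signal 734). The gene tai, which encodes a coactivator of the ecdysone receptor, held an intronic peak on 2L at 9205105 to 9205353 with a signal of 623. Each replicate alone gave 22 and 19 of the 31 genes. The list passed the adjusted threshold in all 7 settings fixed in advance, with adjusted p from 9.31e-09 (Fisher's exact test) to 0.0324 (permutation). Without length matching the ratio was 3.57. With as many pooled entries taken from past the leading 10000, a setting added later, 19 genes held an entry against a mean of 12.4 and the call was lost (adjusted permutation p = 0.137).

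Genes of cytoplasmic ribosomal proteins also held peaks more often, in 23 of 94 (24.5%) against a mean of 12.4 (ratio 1.86; adjusted permutation p = 0.018). RpL32, RpL31, RpL34b and RpS28b had the strongest, all within 500 bp of some annotated TSS, with signals from 230 to 285. The RpL31 peak lay in an intron of clos. This call was lost in 6 of the 7 settings fixed in advance. With the leading peaks of replicate 2 alone 20 genes held a peak (adjusted permutation p = 0.102), and with promoter summits alone 16 did (adjusted permutation p = 0.109).

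Chemosensory receptor genes held peaks less often. Of 179 odorant, gustatory and ionotropic receptor genes, 5 held a peak, against a mean of 29.2 (ratio 0.171; adjusted permutation p = 0.0018), and none of these peaks ranked above 1448. Ir94h, Or85f, Ir31a and Gr93a had the strongest, with signals from 93.0 to 139. This call passed in all 7 settings fixed in advance. Neuronal marker genes were also hit less often, in 2 of 23 against a mean of 8.42 (ratio 0.238; adjusted permutation p = 0.0156). The 2 were elav, whose strongest peak (signal 392) lay in an intron of arg, and Syx1A, whose peak (198) lay in an intron of eIF4EHP. The neuronal call passed with either replicate alone but in none of the other 5 such settings, where the adjusted p reached 0.383 by Fisher's exact test.

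The other 14 lists did not pass the adjusted threshold in the main comparison. Among genes of juvenile hormone and metamorphic timing, 11 of 19 held a peak against a mean of 6.14 (adjusted permutation p = 0.0972), led by Syp (signal 407), br (230), foxo (228) and Eip93F itself (217). Eip93F and br are also on the ecdysone response list. In the timing list 2 genes with a peak shared a summit, so its genes were not all counted independently. The timing list passed with the nearest TSS alone (ratio 2.16; adjusted permutation p = 0.0348) and, without length matching, by Fisher's exact test (ratio 2.92; adjusted p = 0.00172). Of the genes of ecdysteroid synthesis, 4 of 15 held a peak against 4.09 (adjusted permutation p = 1), namely Cyp6u1, mld, ftz-f1 and Npc1a. In cell death, 10 of 24 genes held a peak against 5.63 (adjusted permutation p = 0.166). Diap1, the inhibitor of apoptosis, led with a signal of 296 and 7 summits, followed by hid (219), egr (184) and Dredd (157), whose summit had no match in the list of replicate 2. The summit counted for Dredd lay in the 5′ UTR of su(sable). In autophagy, 8 of 24 held a peak against 5.40 (adjusted permutation p = 0.473), led by Atg17 (240), Atg2 (180), Atg8a (171) and Atg9 (150). With the leading peaks of replicate 1 alone, 12 of the 24 did (adjusted permutation p = 0.0151), and with those of replicate 2 alone 10 did (adjusted permutation p = 0.154).

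Among developmental lists, 16 of 40 genes of wing disc patterning and growth held a peak against 14.1 (adjusted permutation p = 0.805), led by Dll (328), Dad (298), stg (289) and knrl (188). Of the 8 Hox genes, Antp alone held a peak, with 2 summits and a signal of 254 in an intron on 3R at 6914470 to 6914638. The others, lab, pb, Dfd, Scr, Ubx, abd-A and Abd-B, held none (1 of 8 against 3.31; adjusted permutation p = 0.344). Cell cycle genes held peaks in 11 of 35 against 8.06 (adjusted permutation p = 0.473), led by CycB (308), stg (289), Myc (270) and E2f1 (235). Chitin and cuticle genes held peaks in 4 of 41 against 8.98 (adjusted permutation p = 0.166). These were Cht7, pio, knk and Cht2, with signals from 90.6 to 125. With the 1700 strongest peaks, the cuticle list passed on the low side (adjusted permutation p = 0.0288), as it did with 5000 bp on either side of the gene (adjusted permutation p = 0.0204).

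Tissue lists gave the following counts. Glial genes held peaks in 8 of 17 against 4.85 (adjusted permutation p = 0.319), led by nrv2 (230), Gs2 (206), loco (187) and moody (174). Hemocyte genes did so in 5 of 19 against 5.14 (adjusted permutation p = 1), led by ush (1342), msn (364), PPO3 (236) and Fer1HCH (227). Muscle genes did so in 9 of 30 against 9.44 (adjusted permutation p = 1), with Msp300, Mef2, Zasp52 and Tm1 at signals from 164 to 250. Fat body genes did so in 5 of 20 against 5.58 (adjusted permutation p = 1), with Ilp6, Hnf4, mgl and bmm at 137 to 240. Salivary gland glue and puff genes held a peak in 1 of 23, CrebA (104), against 2.28 (adjusted permutation p = 0.805). Testis genes held peaks in 2 of 39, gdl (112) and Mst87F (111), against 5.76 (adjusted permutation p = 0.247). Some of the strongest peaks named for these tissue lists lay within 1000 bp of the listed gene but inside another gene. These were the peaks of moody (in CG4313), PPO3 (l(2)k09913), Fer1HCH (Fer2LCH), Zasp52 (tun), Ilp6 (Raf), Mst87F (lncRNA:CR43300) and gdl (MsrA). MsrA is itself on the ecdysone response list.

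**Figure D3:**
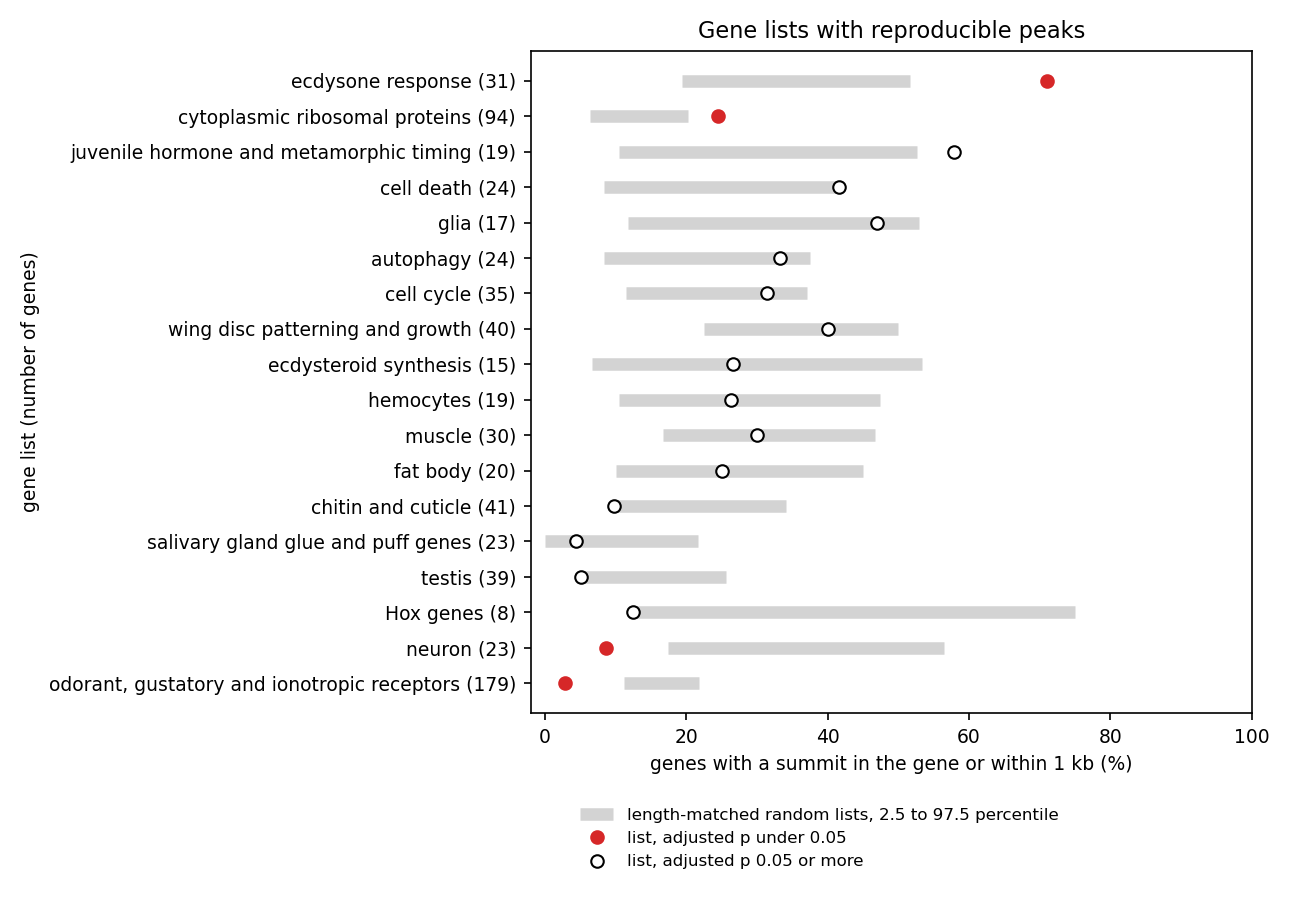
Share of the genes of each list (%, horizontal axis) with a summit in the gene or within 1 kb. Grey bars span the central 95% of 10000 length-matched lists, and filled circles have an adjusted permutation p under 0.05. The ecdysone response list lies at 71.0%, above its grey bar of 19.4 to 51.6%, and the chemosensory receptors lie at 2.79%, below 11.2 to 21.8%.

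The genes with the most summits included Eip75B and tai of the ecdysone response. The overlapping genes Glut4EF and CG46467, on 3R, shared 22 summits, the strongest at 9968255 to 9968471 in an intron of both (signal 387). With the leading peaks of replicate 1 alone they held 13 and with those of replicate 2 alone 25. Eip75B, a nuclear receptor gene of the early ecdysone response on 3L at 17950953 to 18064696, held 20 summits over 113744 bp, and 19 and 17 in the single replicates. The gene bun held 16, tai 15 and the kinase gene Tlk 14. Svil, sbb and tara held 13 each and kirre 12. These genes are long, from 34679 bp (tara) to 394149 bp (kirre). No test was made of these counts. In all, 104 genes held 5 or more summits.

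The tagged gene itself held several peaks. Eip93F spans 21949114 to 22014539 on the forward strand of 3R, with annotated TSSs at 21949114 and 21972379. There were 8 peaks within 10 kb of it, of which 7 lay inside the gene, and the leading lists of replicates 1 and 2 held 8 and 9 there. The strongest lay in an intron at 22003606 to 22003726, upstream of the final exon, with a signal of 217 (ranks 787 and 423 in the replicates). The promoter peak closest to the internal TSS had its summit at 21972342, 37 bp away, with a signal of 148. Intronic summits flanked that TSS at 21970049 (signal 200), 21973247 (120), 21976537 (185) and 21977150 (177). A further intronic summit lay at 21954574 (128), where the 41 bp from 21954554 to 21954594, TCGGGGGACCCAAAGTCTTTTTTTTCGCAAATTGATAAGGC, hold a GATA word. The remaining peak was intergenic, 7619 bp upstream, with its summit at 21941495 (signal 170). The rank of the strongest of these peaks in the reproducible set was 554.

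**Figure D4:**
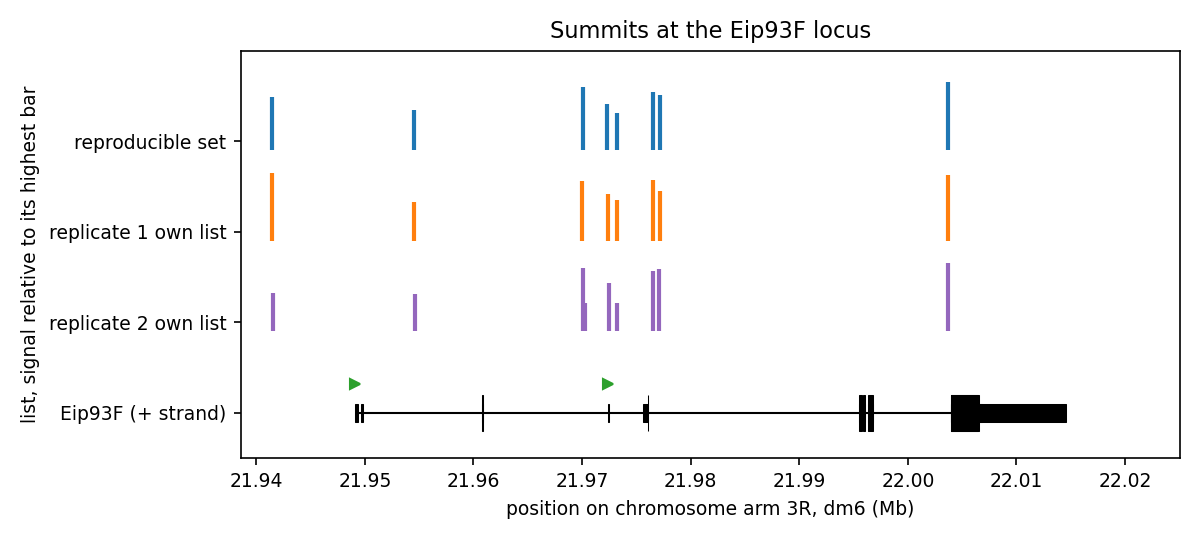
Summits at the Eip93F locus on dm6 (Mb along arm 3R, horizontal axis) in the reproducible set and each replicate's own leading list. Bar heights give the signal relative to the highest bar of the same list, boxes are exons (taller where coding) and triangles are TSSs. The reproducible set has 8 summits, 5 of them between 21970049 and 21977150.

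Sequence words were counted at the summits to see which bases marked them. The GATA word WGATAAG, the core recognised by GATA factors, was found within 50 bp of 6.73% of summits and in 3.31% of flank windows (McNemar exact adjusted p = 6.96e-09). It was present in the replicates' own lists at 5.94% and 7.41% of summits, and passed in all 7 settings fixed in advance. Against random windows matched on annotation class and GC content it was found at 3.41% of positions (McNemar exact adjusted p = 7.66e-09). The word was more frequent at summits outside promoters, at 8.11% of 1800, than in promoters, at 5.18% of 1601 (Fisher's exact p = 0.000754).

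Of the other 16 preset words, 3 were more frequent at summits than in flanks. The TATA box was more frequent in promoters, at 11.6% of summits, than elsewhere (Fisher's exact p = 0.000394). It was found at 9.70% of all summits against 4.48% (McNemar exact adjusted p = 6.57e-16), the homeodomain core TAATTA at 8.94% against 5.60% (2.14e-08) and the poly(A) tract at 8.67% against 6.62% (0.00577). None of these 3 passed against windows matched on class and GC content, where the McNemar exact adjusted p was 0.11 for the TATA box (8.29% of matched windows), 0.11 for the homeodomain core (10.4%) and 0.653 for the poly(A) tract. In that comparison the GAGA word was higher at summits, at 2.18% against 0.853% (McNemar exact adjusted p = 2.81e-05), as was the CA repeat, at 2.53% against 1.38% (0.00388). Against flanks both went the other way, at 2.75% and 3.22% of flank windows, without passing (McNemar exact adjusted p = 0.21 and 0.493), and GAGA was called lower with replicate 1 alone (0.00431). Against matched windows the nuclear receptor half-site AGGTCA was lower, at 1.71% against 2.68% (McNemar exact adjusted p = 0.0344). In the main comparison no preset word was lower at summits than in flanks by McNemar's exact test, with 0 at an adjusted and 0 at an unadjusted p under 0.05. AGGTCA was called lower with flanks at 1000 bp (McNemar exact adjusted p = 0.011) and with replicate 2 alone (0.0104). The DREF word TATCGATA missed the threshold, at 0.647% against 0.279% (McNemar exact adjusted p = 0.0543), and passed with each replicate alone, with flanks at 1000 bp and with windows of 100 bp to either side. Motif 1 also missed it, at 0.588% against 0.279% (McNemar exact adjusted p = 0.0543), and passed with those wider windows (1.62e-07). The remaining 8 words (Zelda, AP-1, Grainyhead, the palindromic E-box, PAR bZIP, Stat92E, Scalloped and Runt) passed with neither control.

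Summits were richer in A and T than their surroundings. The GC content of the 101 bp around summits was 36.0% ± 9.71 (SD across 3401 peaks), against 42.7% ± 7.76 in the flanks, and 68.6% of peaks were lower at the summit. The dip was present at promoter (35.4 against 44.1%), intron (36.8 against 41.5%) and intergenic summits (34.0 against 41.2%), and small at the 106 exon summits (40.4 against 41.1%).

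Of 2080 6-mers, 278 were more frequent at summits than in flanks and 572 less frequent by McNemar's exact test. Among the 278, 202 had 5 or 6 A or T bases. The 10 with the smallest adjusted p were ATTTTA, AATATA, AAATAT, TTAAAA, TATTAA, ATATAA, ATATTA, AAAATA, TAAATA and AAATAA. The first of them was found at 26.6% of summits and in 13.5% of flank windows (McNemar exact adjusted p = 2.05e-43), but in 23.7% of windows matched on class and GC content (McNemar exact adjusted p = 0.0441). TTAAAA and TAAATA did not pass against matched windows, and the other 8 named words passed there with smaller differences than against flanks. Against windows matched on class and GC content, 76 6-mers were higher and 71 lower, and 29 and 52 of these were also called against flanks. The leading word was then CTTATC, the reverse complement of GATAAG, found only at the summit for 322 peaks and only in the matched window for 150 (McNemar exact adjusted p = 3.58e-12). It was followed by ACAGTG, with 260 and 133 such peaks (1.5e-07). Both were also higher than in flanks, and were named after their values were seen.

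**Figure D5:**
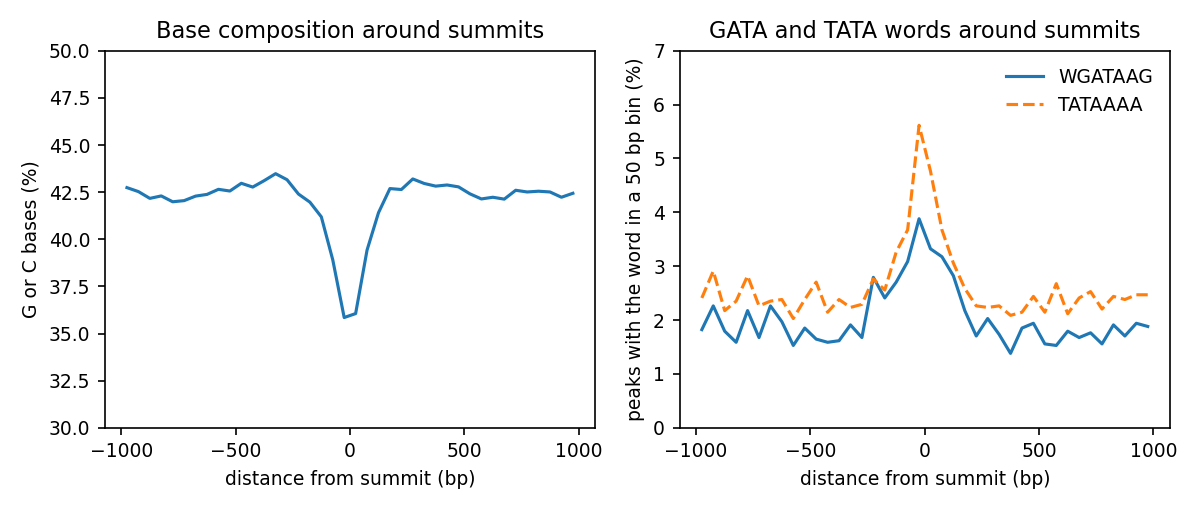
Base composition (left, % G or C) and share of peaks with the GATA or TATA word (right, %) in 50 bp bins from 1000 bp upstream to 1000 bp downstream of 3401 summits. GC content falls to 35.9% beside the summit from 42.7% at the edge, and the GATA word rises from 1.82% to 3.88% of peaks. The left vertical axis starts at 30%.

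On the older build dm3 the reproducible set held 3198 peaks, against 3401 on dm6. On dm3, the arms 2L, 2R, 3L, 3R and X held 607, 578, 701, 738 and 560 peaks, and chromosome 4 held 7. On dm6 these counts were 646, 628, 737, 785, 597 and 8. The X had 17.51% of the peaks on dm3 and 17.55% on dm6. Outside these arms dm3 had 7 peaks, and dm6 had 0. No coordinate was compared across builds.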

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

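These peaks were picked out after the values had been seen, and no test was chosen for them. The dm3 lists hold peaks outside the chromosome arms, which count in the dm3 totals and in the dm3 agreement of the replicates and were not otherwise analysed here. In the dm3 reproducible set, 2 peaks lay on the mitochondrial genome, the stronger with a signal of 1116 and a rank of 4 of 3198, at 18902 to 19257 on dm3. A further 5 lay on unplaced sequence, the strongest with a signal of 207 and a rank of 601. On dm6 the reproducible set has no mitochondrial peak, but the list of replicate 2 has 1 mitochondrial entry, at 19178 to 19498, with a signal of 530 and a rank of 4. The signals of different lists are not comparable. No explanation of these peaks was tested. With 1 group of 2 replicates there was no comparison of groups and no test of a sample against its group.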

How the results depend on the processing

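The comparisons with lower-ranked pooled entries and the direct comparison of the replicates' leading peaks were chosen after the data were seen, and all other alternatives before. No paired analysis was possible because there was a single group. The number of peaks and 2 replicates limit what could be resolved, and the depth is unknown. Where a value moved, the cause was not tested unless stated. The promoter excess and the exon and intergenic deficits passed in all 6 settings fixed in advance, with promoter shares from 36.8 to 58.6%. The promoter signal difference passed in none of its 6, and at the Eip93F locus the single replicates gave 8 to 9 peaks.

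The share of reproducible peaks in the leading lists of replicates 1 and 2 was 83.1% and 81.7% with 1 bp of overlap, 78.1% and 71.2% with 50% reciprocal overlap, and 78.5% and 75.3% with summits within 100 bp. The 1700 strongest peaks were set against only the 1700 leading peaks of each replicate. The share was then 83.2% for replicate 1, and rho, taken from the full lists, was 0.528. With the other replicate's leading peaks in place of the reproducible set it was 65.0% for replicate 1 and 65.6% for replicate 2, by the construction of the set. The intron share, not different from random in the main comparison, was 44.2% (above random) with promoters of 250 bp, 31.2% (below) with 1000 bp, 39.9% with protein-coding TSSs, 38.25 to 39.7% in single replicates, and 39.0% against lower-ranked entries, below their 46.1%. The X to autosome ratio was 1.07 with the 1700 strongest peaks.

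Lists called higher (2 in the main comparison) numbered 1 with promoter summits, 5 with Fisher's exact test, which does not match length, 1 with 5000 bp flanks, 1 with the 1700 strongest peaks and 0 with entries past the leading 10000, and ran from 1 to 3 in single replicates. Lists called lower (2) numbered 1 with promoter summits, 1 with the nearest TSS alone and 1 with entries past the leading 10000. In some settings the number stayed at 2 but the lists differed, with 1 shared with the main comparison for those higher with the nearest TSS (ribosomal proteins lost, juvenile hormone and timing gained) and for those lower with Fisher's exact test, 5000 bp flanks and the 1700 strongest peaks. In single replicates both lower lists were shared. Preset words called lower (0) numbered 1 with flanks at 1000 bp, 1 against matched windows and 1 in each single replicate. This word was the nuclear receptor half-site, except with replicate 1 alone, where it was GAGA. The 6-mers called lower numbered 342 with 25 bp windows. Against matched windows 76 were higher and 71 lower.

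Ratios to random lists that changed side of 1, none of them past the threshold in either setting, were as follows. With promoter summits they were 0.516 for wing disc, 1.47 for fat body and 0.736 for cell cycle genes. With the nearest TSS they were 1.34 for fat body and 1.23 for hemocytes. With Fisher's exact test they were 1.34 for ecdysteroid synthesis, 1.26 for fat body, 1.51 for muscle and 1.32 for hemocytes. With 5000 bp they were 1.32 for ecdysteroid synthesis, 1.20 for fat body and 1.18 for hemocytes. With the 1700 strongest peaks they were 1.21 for fat body, 1.46 for muscle and 1.25 for hemocytes. In single replicates they ran from 0.493 to 1.21 for ecdysteroid synthesis and from 0.968 to 1.06 for muscle. With entries past the leading 10000 they were 1.17 for ecdysteroid synthesis, 0.972 for cell death, 1.45 for cuticle and 1.05 for fat body.

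Differences between summits and control, in percentage points, also changed sign. With 25 bp windows they were 0.162 for AP-1 and 0.0735 for Runt. With 100 bp windows they were 0.882 for GAGA, 0.0147 for AP-1, 0.0441 for PAR bZIP and -0.382 for Stat92E. With flanks at 1000 bp they were 0.0294 for GAGA, 0.0147 for Zelda, 0.397 for AP-1, 0.0441 for the CA repeat and -0.470 for Stat92E. Against matched windows they were 1.32 for GAGA and 1.15 for the CA repeat, both past the threshold, and 0.470 for Zelda, 0.441 for AP-1, 0.0294 for the E-box, -1.47 for the homeodomain core and -0.735 for Stat92E. With the 1700 strongest peaks they were 0.118 for Zelda, 0.147 for AP-1 and -0.0588 for Scalloped. In single replicates they ran from -0.750 to 0.0441 for GAGA, from -0.0588 to 0.25 for AP-1, from 0.147 to 0.309 for PAR bZIP, from -0.588 to 0.176 for Stat92E, from -0.0147 to 0 for Scalloped and from -0.235 to 0.235 for Zelda. Of these differences only GAGA and the CA repeat against matched windows passed as higher, and GAGA in replicate 1 alone (-0.750) as lower.

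Of 144 values for gene lists in other settings, 100 kept their call and side, 21 changed side, 9 more passed only there and 14 passed only in the main comparison. Of 119 for preset words these counts were 80, 28, 9 and 2. A value that changed side was counted only there, even where its call changed too. Against matched windows this held for the homeodomain core, which lost its call, and for GAGA and the CA repeat, which gained one. Of 70 for the leading 6-mers, 68 kept their call and 2 lost it.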

Other observations

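The GC-matched words and the lower-ranked entries on chromosome 4 were chosen as tests of an explanation only after their results had been seen, and the further gene lists were written after the values of single genes had been seen. For those 6 lists the test was as for the others, adjusted over the 6. Heat shock and chaperone genes held peaks in 11 of 19 against a mean of 3.46 in length-matched lists (adjusted permutation p = 0.0012, from the smallest p the lists can give), led by Hsp27 (signal 1013), Hsp83 (302), Hsc70-5 (215) and Hsp23 (186). This list was written with Hsp27 already known to hold a leading peak, so its count is not independent. Without the 6 small heat shock genes that lie together on 3L, 5 of 13 held a peak against 2.69 (permutation p = 0.219). Polycomb and Trithorax group genes held peaks in 11 of 25 against 7.28 (adjusted permutation p = 0.225), led by ph-p (1097), osa (986), ash1 (969) and brm (408). With the leading peaks of replicate 1 alone 14 did (adjusted permutation p = 0.0216), and with those of replicate 2 alone 11 did (adjusted permutation p = 0.34). The peak counted for ash1 lies in its shared upstream region with CG14100.

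Genes of insulin and TOR signalling held peaks in 12 of 29 against 7.59 (adjusted permutation p = 0.19), led by REPTOR (458), Sesn (406), ImpL2 (249) and Ilp6 (240). Circadian clock genes did so in 4 of 16 against 4.80 (adjusted permutation p = 1), with 11 summits at vri and 5 at sgg. Antimicrobial peptide and immune receptor genes did so in 4 of 25 against 3.82 (adjusted permutation p = 1), namely the signalling genes imd, cact, Rel and Dif, and no antimicrobial peptide gene of the list held a peak. The peak counted for imd lay in an intron of Dp1. After the leading peak at Chro (1073) had been seen, but before the list was tested, it was predicted that genes of insulator and architectural proteins, such as Chro, held peaks more often. They did so in 8 of 18 against 4.42 (adjusted permutation p = 0.19), which does not pass.

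Words at summits could come from their base composition alone. Against windows of the same GC content and class the TATA box (9.70 against 8.29%) and the homeodomain core (8.94 against 10.4%) no longer passed (smaller McNemar exact adjusted p = 0.11). The TATA excess shrank and that of the homeodomain core changed sign, which is consistent with composition as a source of at least part of both. A part played by promoter TATA boxes stays open, since that word was more frequent at promoter summits than at others (Fisher's exact p = 0.000394). The GATA word kept its excess against windows matched on GC content and class (McNemar exact adjusted p = 7.66e-09), which argues against composition for that word. It also kept it at summits outside promoters (McNemar exact p = 4.14e-08), which argues against a word of promoters. The hypothesis that sites bound by GATA factors lie near part of the summits was not tested, and binding data for a GATA factor from the same stage would test it.

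The excess of ecdysone response genes may reflect chromatin that is accessible for other reasons, which would also raise weaker entries. With 3401 pooled entries past the leading 10000, 19 of the 31 genes held an entry against a mean of 12.4 (permutation p = 0.0152, adjusted p = 0.137 over the 18 lists). Among these entries, outside the reproducible set, the list thus also lay above its random mean, at a ratio of 1.53 against 2.06. It passed there only before adjustment, and a shared source of this kind stays open. The entries came from the same precipitation, so they cannot separate accessible chromatin from weaker binding. A leftover effect of gene length stays open too. Promoter summits alone kept the excess, with 13 genes against 5.72 (permutation p = 0.0036). That count used the same span bins and any annotated TSS of a gene, so it could still depend on length. The chemosensory receptors were also hit less often among those entries, in 7 of 179 against 21.8 (adjusted permutation p = 0.0072). No chromatin accessibility data were analysed here.

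Chromosome 4 held 0.235% of the reproducible peaks but 1.72% of the 26599 lower-ranked pooled entries (exact interval 1.57 to 1.88%), against 0.98% of the length of the arms (odds ratio 0.135; Fisher's exact p = 2.34e-15). A shortage of entries of any rank on that chromosome is thus argued against, since lower-ranked entries were more frequent there than its length gives. Fewer TSSs are argued against too, as peaks were also fewer than the share of TSS positions gives (exact binomial p = 5.18e-05). With each replicate's own list the chromosome had 10 and 9 peaks. What stays open is how the control alignment and mappability, neither analysed here, act on the ranking of entries on this chromosome.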
